A study of Caenorhabditis elegans with 6 samples.

How the data were processed

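Whole wild-type worms from 6 libraries were sequenced, 3 labelled as vehicle treated and 3 as treated with ilimaquinone, and the groups and replicate numbers were taken from the sample titles. Per the labels' protocols, each library was made separately from 1 µg of total RNA with a stranded poly(A) kit. The labels do not say that libraries of a group came from separate cultures, so the p-values measure only the spread between these samples. Per the submitters' processing notes, the tools included bcl2fastq 2.20.0, HISAT2 2.1.0 and SAMtools 1.9, and the genome build was WBcel235. The counting program, its strand setting and the annotation release are not given in the sources used here.

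The authors deposited a gene table and a transcript table, each with a read count, an FPKM and a TPM column per library, per the file headers. The values headed as read counts are called estimated counts here. Their unit is not settled, since the counting program is not given and the check that follows cannot decide it. The deposited estimated counts were whole numbers. In each library, 17434 to 18698 transcripts were checked, those with fewer than 200 counts. All had a count not below the value implied by FPKM and length, and at most 1 above it, within a tolerance of 0.02 counts. Counts rounded up from coverage pass this check, but so would tallies of reads from which the FPKM was computed. The check therefore cannot tell which of these the counts are. The FPKM values that the authors deposited were used in that check only, and the TPM values that the authors deposited were used for 1 alternative test. The test had been planned for read counts and was kept for estimated counts, which were already whole and needed no further rounding.

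Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr by group, TMM factors, glmQLFit and glmQLFTest, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use TMM-scaled library sizes, and standard errors are the fold change divided by the square root of its F statistic. Group values are mean ± SD over 3 libraries. Total counts were 32155192 to 39244786 per library, and the biological coefficient of variation was 28.4%. In data simulated from the real means, library sizes and dispersions, the gene test on 16268 genes recovered 27% of genes changed 2-fold and 80% of genes changed 4-fold, and 10.1% of its calls were unchanged genes, above the nominal level. The transcript test on 21670 transcripts recovered 2% and 25%, and 15.6% of its calls were unchanged. Each rate comes from a single draw with 200 changed genes or transcripts, where 12 and 5 unchanged ones were called. Genes were drawn independently, without a shared shift in any library, so the rates may not carry over to these data.

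Lists of genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, over the 30 lists with at least 3 tested members, and again with an estimated correlation and with fry. The 30 lists, the tests, the naming rule and all alternatives but 1 were fixed before the data were examined. The alternative added afterwards counted called members of each list without vehicle replicate 1. Mitochondrially encoded genes were matched by chromosome, since their symbols in the table differ from those listed. The naming rule took, in each direction, the 12 called genes with the largest fold change among those with separated groups and a mean of at least 5 CPM, the 4 most abundant called genes, and the called member of each list with the smallest adjusted p, or the member with the smallest p where none was called. It also took sod-3, gst-4, hsp-16.2, hsp-4, hsp-6, mtl-1, daf-16, skn-1, hsf-1, lgg-1, unc-54 and myo-3. Other genes, such as gst-7, nit-1, gpx-3, gpx-5, vha-5, dhs-12, lin-1 and the pals genes, were chosen after their values were seen.

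The alternatives were DESeq2 1.42.0 (Wald test), DESeq2 size factors, upper-quartile factors or library size alone in edgeR, no filter on low counts, a stricter filter (at least 1 CPM in 3 libraries and 50 counts in all), the replicate number as a block, limma-trend on log2(TPM + 1), and leaving out each library in turn. Gene positions are those of the deposited transcript table on WBcel235, taken from the first to the last base of a gene's transcripts, and 64 of 71 named loci lay within 1000 bases of the Ensembl release 115 annotation at both ends. Among the others were the called genes sod-3 and spe-38, whose deposited loci end 8252 and 3791 bases past the Ensembl ones. Of 20042 WormBase identifiers in the table, 19879 matched the gene name table used.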

Results

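Poly(A) RNA of whole wild-type Caenorhabditis elegans was sequenced from 6 libraries, 3 from animals kept in the vehicle medium and 3 from animals that also received ilimaquinone. Ilimaquinone is a sesquiterpenoid quinone made by marine sponges and is known for breaking up the Golgi apparatus of cultured cells. Animals entered treatment at the last larval stage and stayed in it for 11 days at 20 °C, with ilimaquinone at 100 µM in the treated group. Both groups received 200 µM FUDR, an inhibitor of DNA synthesis that keeps worms from producing progeny, and 100 µg/mL ampicillin. The vehicle libraries held 32284669, 34206575 and 32656803 estimated counts for replicates 1, 2 and 3. The ilimaquinone libraries held 39244786, 32155192 and 36949358. Of 47656 genes listed, 27237 had a count in at least 1 library and 16506 were abundant enough to test.

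Vehicle replicate 1 stood apart from the other libraries. On the first principal component of log2 CPM, which held 57.6% of the variance, it lay at -98.8, against 0.1 and -26.5 for vehicle replicates 2 and 3 and 25.1 to 54.1 for the ilimaquinone libraries. Genes of the germline were among those that differed there: the summed level of 30 oocyte and germline markers was 4404 CPM, against 1158 and 1403 CPM in the other vehicle libraries and 681 to 986 CPM with ilimaquinone. Neuron markers were lowest there, at 2233 CPM against 3752 and 3782 CPM in the other vehicle libraries. Which genes drive the component was not tested. The ilimaquinone libraries correlated with each other at 0.981 to 0.984 across genes (Pearson, log2 CPM), and vehicle replicate 1 correlated with vehicle replicates 2 and 3 at 0.942 and 0.953. Vehicle replicate 2 was as close to the ilimaquinone libraries, at 0.972 to 0.975, as to vehicle replicate 3, at 0.974. Genes are not independent replicates, so these correlations describe the libraries only. No pair of libraries was close enough to be a duplicate, the smallest chi-square per gene between any pair being 29.9.

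The comparison of ilimaquinone with vehicle asks which genes respond to the compound in adult animals. Genes for enzymes that modify and clear foreign compounds, genes for superoxide dismutases and glutathione peroxidases and a group of cuticle collagens were among those that rose with ilimaquinone. The cytochrome P450 gene cyp-33B1 rose from 5.06 ± 1.64 CPM to 174 ± 14.9 CPM (mean ± SD, n = 3 per group), and the glutathione S-transferase gene gst-4 rose from 14.3 ± 0.601 to 45.6 ± 5.51 CPM. Fewer genes fell in edgeR, among them T26A8.4, from 60.9 ± 3.22 to 25.9 ± 1.05 CPM, and Y58A7A.3, from 387 ± 31.7 to 203 ± 5.12 CPM. Markers of oocytes, sperm and yolk had lower medians with ilimaquinone, but as lists they were also highest in vehicle replicate 1, and 1 of them, spe-38, passed the test over all genes.

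In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, called edgeR here, 188 genes were higher and 54 lower at an adjusted p under 0.05. Of these 242 genes 143 differed at least 2-fold, 118 higher and 25 lower. All 242 had the 3 ilimaquinone libraries on one side of the 3 vehicle libraries, as did 30.8% of all tested genes. Random labels give 10% on average, but genes share the same libraries, so 1 labelling can lie far from that. Protein-coding genes made up 239 of the calls. The share of higher genes was 77.7% in edgeR and 48.2% in DESeq2's Wald test, which called 879 higher and 943 lower. The counts depended on single libraries. Without vehicle replicate 1, 2 or 3 there were 451, 116 or 93 higher genes and 274, 25 or 21 lower genes. Without ilimaquinone replicate 1, 2 or 3 edgeR called 18, 23 or 11 genes higher and 0, 1 or 0 lower, with 2130, 1911 and 2509 genes at an unadjusted p under 0.05; DESeq2 was not run without a library. The 2-fold count was 275 without vehicle replicate 1 and 18, 24 or 11 without ilimaquinone replicate 1, 2 or 3. In each of these 6 fits all 242 genes kept the sign of their fold change. Their groups do not overlap, so leaving out 1 library could hardly turn a sign, and the kept signs are no added support. Without vehicle replicate 1 the test again called 241 of them.

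**Figure D1:**
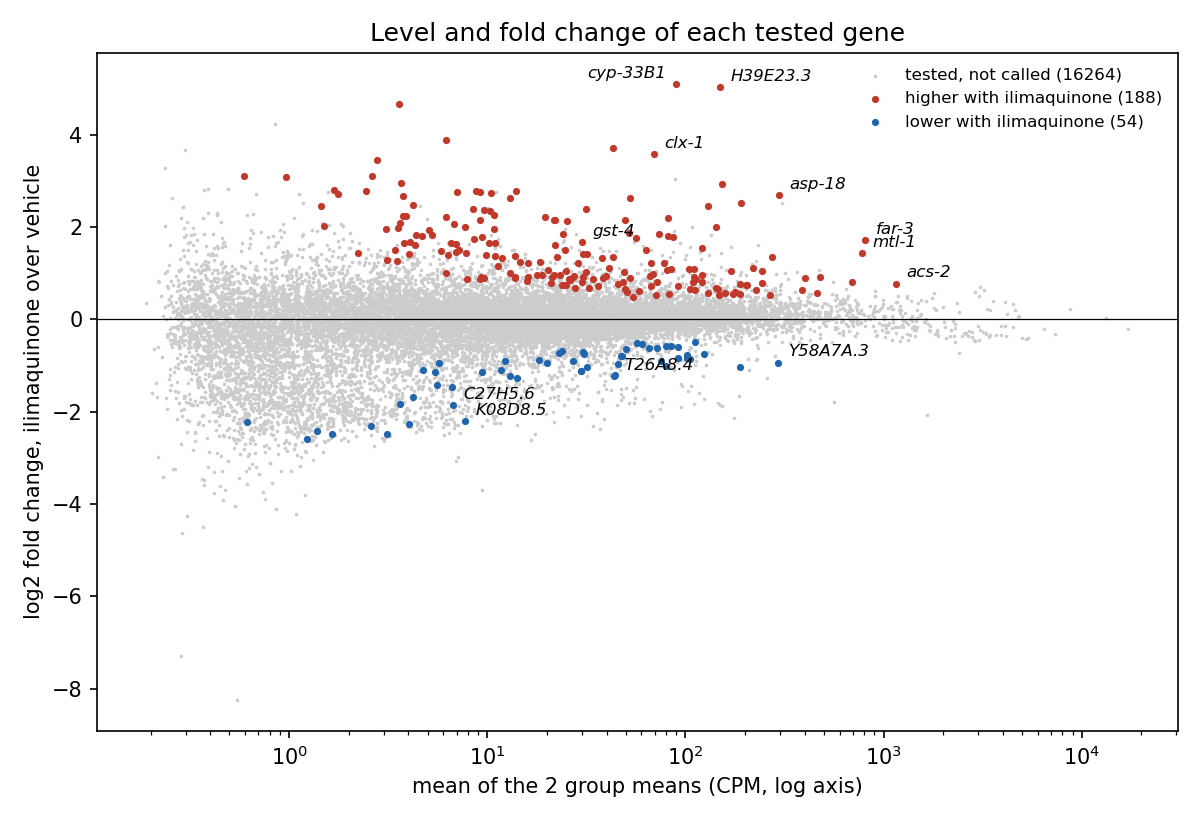
Each point is 1 of 16506 tested genes, with the mean of the 2 group means in CPM on a log axis against the log2 fold change of ilimaquinone over vehicle. Red points are the 188 genes called higher and blue points the 54 called lower; cyp-33B1 and H39E23.3 lie highest among the called genes, at 5.10 and 5.04.

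The gene that rose most was cyp-33B1 (gene 182888, chromosome V, 9041330 to 9043677, build WBcel235), with a log2 fold change of 5.10 ± 0.25 (SE, edgeR adjusted p = 0.00162). H39E23.3 (gene 3565355, chromosome V, 14107811 to 14110051), an uncharacterized gene, rose from 8.85 ± 1.32 to 291 ± 43.5 CPM. Its log2 fold change was 5.04 ± 0.18 (edgeR adjusted p = 4.51e-04). Its neighbour D1086.9 rose by 3.72 ± 0.34 and F19B10.6 on chromosome II by 3.90 ± 0.40, both on the log2 scale. The collagen-like gene clx-1 rose by 3.57 ± 0.35. The aspartic protease gene asp-18 (gene 191310, chromosome V, 18730174 to 18731679) rose from 79.9 ± 17.2 to 516 ± 50.2 CPM, a log2 fold change of 2.69 ± 0.18 (edgeR adjusted p = 0.00455). F14F9.2, F56D6.9, spp-21, alh-2, C02E7.7 and fbxa-75 rose by 2.75 to 2.93 on the log2 scale. Of these alh-2 encodes an aldehyde dehydrogenase and spp-21 a saposin-like protein. The most abundant gene that rose was acs-2, an acyl-CoA synthetase gene of fatty acid oxidation, at 851 ± 79.8 against 1458 ± 66.6 CPM. Next came far-3, a fatty acid and retinol binding protein gene, at 377 ± 109 against 1240.5 ± 116 CPM. The metallothionein gene mtl-1 stood at 419 ± 108 against 1132 ± 147 CPM and W05H9.1 at 507 ± 83.8 against 885 ± 12.9 CPM.

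Among called genes of at least 5 CPM, K08D8.5 and C27H5.6 fell most, by 2.21 ± 0.25 and 1.85 ± 0.32 on the log2 scale. K08D8.5, a gene with a CUB domain (gene 178243, chromosome IV, 12910647 to 12912145), fell from 12.7 ± 3.64 to 2.74 ± 0.343 CPM (edgeR adjusted p = 0.0171). T26A8.4 (gene 177643, chromosome IV, 8428957 to 8432893) had a log2 fold change of -1.23 ± 0.10 (edgeR adjusted p = 0.00541). Y45F10D.6, clec-51, math-38, R03H10.6, C06B3.7, Y39A3A.3 and math-4 fell by 1.13 to 1.47 on the log2 scale. The metal-responsive genes numr-1 and numr-2 both had a log2 fold change of -1.11 ± 0.17. They are near-identical neighbours with almost equal levels in every library, so each value is uncertain. The most abundant genes that fell were Y58A7A.3 and its neighbour Y58A7A.4, by 0.93 ± 0.09 and 1.04 ± 0.09 on the log2 scale. W01F3.2 fell by 0.75 ± 0.10 and ugt-29 by 0.49 ± 0.08. The loci of gst-4, sod-3, akt-1, far-3, spe-38, vha-5, nit-1, clec-51, C27H5.6, Y45F10D.6, numr-1 and numr-2 each overlap another tested gene, as do those of enpl-1, skn-1, daf-16, hsp-16.2 and lgg-1, which were not called. The strand setting of the counting is not given in the sources used here, so which gene the reads of an overlap were counted for is uncertain. For gst-4 the overlapping gene is dhs-12, which had a log2 fold change of 0.64 ± 0.17 (edgeR adjusted p = 0.123).

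**Figure D2:**
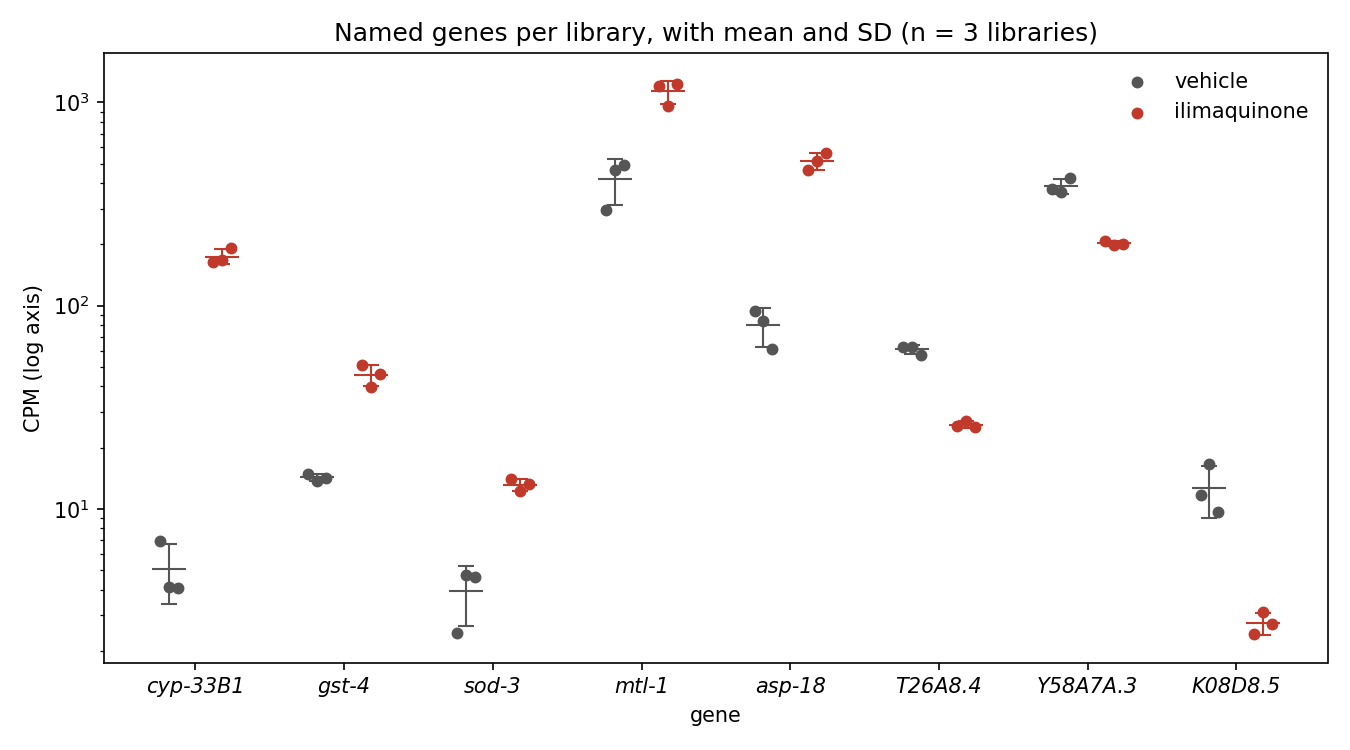
Level of 8 genes in each library, in CPM on a log axis, with vehicle libraries in grey and ilimaquinone libraries in red; points are libraries, the long dash is the group mean and the bars its SD (n = 3). In each gene the 3 libraries of one group lie apart from those of the other, as for gst-4 at 13.7 to 14.9 CPM against 39.8 to 50.8 CPM.

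More detoxification genes rose than fell. Cytochrome P450 enzymes oxidize foreign and endogenous compounds. Of 72 tested, 5 rose and none fell, and 11 rose and 1 fell when p was adjusted over the list alone. The median log2 fold change of this list was 0.28 (camera adjusted p = 7.99e-05; adjusted p = 0.624 with an estimated correlation). Glutathione S-transferases and UDP-glucuronosyltransferases attach glutathione or sugars to such compounds. Of 102 tested, 7 rose and 2 fell, or 28 and 6 adjusted over the list alone. Their median was 0.36 (camera adjusted p = 8.37e-08; adjusted p = 0.503 with an estimated correlation). The genes that rose included gst-4 (gene 177886, chromosome IV, 10142135 to 10143099), with a log2 fold change of 1.68 ± 0.13 (edgeR adjusted p = 0.00541), and ugt-26 fell by 0.62 ± 0.10 on the log2 scale. SKN-1, the worm counterpart of the Nrf transcription factors, drives several of these genes. Of its 15 tested targets 14 had a positive fold change and 3 rose, gst-4, gst-7 and nit-1, or 8 adjusted over the list alone. The median was 0.87 (camera adjusted p = 7.57e-10; adjusted p = 0.224 with an estimated correlation). The genes gst-4, gst-5, gst-7, gst-10, gst-12, gst-13, gst-30, gst-38 and ugt-11 belong both to the SKN-1 list and to the transferase list. ABC drug transporters pump compounds out of cells. Of 23 tested, pgp-3 rose by 0.66 ± 0.11 and pgp-8 fell by 0.82 ± 0.13 on the log2 scale, or 3 rose and 3 fell adjusted over the list alone. The list had a median of -0.09, or 0.06 without vehicle replicate 1 (camera adjusted p = 0.953). Without vehicle replicate 1 the higher members were 8 P450 genes, 17 transferase genes, 6 SKN-1 targets and 2 transporters, and the lower ones were 4 transferase genes and 2 transporters.

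Several antioxidant genes rose. Of 26 antioxidant enzyme genes, sod-5, sod-3, gpx-3 and gpx-5 rose, or 8 adjusted over the list alone, and none fell. The list median was 0.15 (camera adjusted p = 9.00e-05; adjusted p = 0.575 with an estimated correlation). The cytosolic superoxide dismutase gene sod-5 rose from 0.536 ± 0.136 to 4.69 ± 0.499 CPM. The mitochondrial superoxide dismutase gene sod-3 (gene 181748, chromosome X, 17092718 to 17102558) rose from 3.93 ± 1.27 to 13.2 ± 0.909 CPM, a log2 fold change of 1.74 ± 0.27 (edgeR adjusted p = 0.0398). The deposited locus of sod-3 spans lido-1, which had a mean of 187.8 counts against 301.3 for sod-3. The gene sod-3 is also a classical output of the transcription factor DAF-16, which acts when insulin signalling is low. Of 14 DAF-16 targets, mtl-1 (log2 fold change 1.43 ± 0.21, edgeR adjusted p = 0.0365) and sod-3 rose, or 4 genes adjusted over the list alone. The median was 0.20 (camera adjusted p = 0.00547; adjusted p = 0.503 with an estimated correlation), and it was 0.49 without vehicle replicate 2 and 0.13 without ilimaquinone replicate 2. The regulators themselves gave log2 fold changes of 0.13 ± 0.08 for daf-16, 0.30 ± 0.11 for skn-1 and -0.10 ± 0.09 for hsf-1, none past the test. The calls without vehicle replicate 1 were 7 antioxidant genes and 4 DAF-16 targets, all higher.

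The chaperone lists held no gene called over all genes in edgeR. None of 19 genes for endoplasmic reticulum chaperones and the unfolded protein response passed the edgeR test over all genes, with 9 higher at an unadjusted p under 0.05 and 7 called by DESeq2. In this list 18 genes had a positive fold change and 7 rose adjusted over the list alone. The median was 0.18 (camera adjusted p = 9.05e-05; adjusted p = 0.503 with an estimated correlation). Its member with the smallest p, enpl-1, which encodes endoplasmin, was at 741 ± 49.4 against 1061 ± 27.5 CPM (edgeR adjusted p = 0.0538, and 0.0246 without vehicle replicate 1). The BiP gene hsp-4 had a log2 fold change of 0.13 ± 0.19, which was -0.03 without vehicle replicate 2 and -0.07 without ilimaquinone replicate 3. No member of the 15 cytosolic heat shock protein genes was called, also over the list alone, with 1 at an unadjusted p under 0.05 and 0 called by DESeq2. Their median was 0.19 (camera adjusted p = 0.224, but 5.42e-04 without vehicle replicate 3 and 0.0441 without ilimaquinone replicate 2). That median was 0.33 and 0.26 in these fits, 0.04 without vehicle replicate 2, -0.01 without ilimaquinone replicate 3, and 0.09 without vehicle replicate 1, where the camera direction was down (adjusted p = 0.964). Their member hsp-16.2 stood at 625 ± 128 against 617 ± 33.9 CPM. In the endoplasmic reticulum list 4 genes were called higher without vehicle replicate 1.

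The fixed lists of secretory and mitochondrial genes held no gene called over all genes in edgeR. Of 34 genes of the Golgi and early secretory pathway 1 rose adjusted over the list alone, 6 had an unadjusted p under 0.05 and DESeq2 called 4. The list median was 0.08 (camera adjusted p = 0.166, but 0.00421 without a filter on low counts). The COPII coat gene sec-24.1 was at 193 ± 8.12 against 257 ± 0.959 CPM (edgeR adjusted p = 0.0638, and 0.0325 without vehicle replicate 1). The 12 mitochondrial chaperones and proteases had no call over the list alone either, 3 genes at an unadjusted p under 0.05 and 1 called by DESeq2 (median 0.03, camera adjusted p = 0.572), and hsp-6 had a log2 fold change of 0.38 ± 0.13. The 41 nuclear genes of the respiratory chain had 0 genes past edgeR over the list alone, 0 at an unadjusted p under 0.05 and 0 in DESeq2 (median -0.02, or 0.01 without ilimaquinone replicate 2, camera adjusted p = 0.908). Of 11 tested mitochondrially encoded genes 2 rose adjusted over the list alone, 5 had an unadjusted p under 0.05 and DESeq2 called 2. Their median was 0.23 (camera adjusted p = 0.101). It was 0.36 without ilimaquinone replicate 3 (camera adjusted p = 0.0033) and 0.30 with a stricter filter on low counts (camera adjusted p = 0.00937). The fit without vehicle replicate 1 called 1 Golgi gene higher and 1 mitochondrial chaperone or protease gene lower.

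Lists of reproductive markers had lower medians with ilimaquinone, but only 1 gene was called by edgeR over all genes, and the lists were highest in vehicle replicate 1. Vitellogenins, the yolk proteins made for oocytes, had a median log2 fold change of -1.36 over 6 genes (camera adjusted p = 7.35e-04; adjusted p = 0.624 with an estimated correlation). None passed the edgeR test over all genes, 5 fell adjusted over the list alone, 5 had an unadjusted p under 0.05 and DESeq2 called 3. The gene vit-2 was at 2669 ± 2196 against 636 ± 175 CPM (edgeR adjusted p = 0.133). The 30 germline and oocyte markers had a median of -1.52 (camera adjusted p = 7.57e-10; adjusted p = 0.624 with an estimated correlation). None was called by edgeR over all genes and 23 fell adjusted over the list alone, with 25 at an unadjusted p under 0.05 and 22 called by DESeq2. Their member mex-3, which encodes an RNA-binding protein, was at 98.5 ± 22.9 against 62.5 ± 4.26 CPM (edgeR adjusted p = 0.13, and 0.048 without vehicle replicate 2). All 61 sperm markers had a negative fold change, with a median of -1.80 (camera adjusted p = 2.46e-14; adjusted p = 0.624 with an estimated correlation). The gene spe-38, which sperm need for fertilization, fell by 2.58 ± 0.44 on the log2 scale, the 1 edgeR call of that list over all genes and also adjusted over the list alone. At an unadjusted p under 0.05 there were 42 lower sperm markers, and DESeq2 called 26 lower. Without vehicle replicate 1 the medians were -0.76 for vitellogenins, -0.59 for oocyte and germline markers and -1.04 for sperm markers. Of 3 early embryonic markers none was called over all genes by edgeR and vet-1 fell adjusted over the list alone, with 1 gene at an unadjusted p under 0.05 and 1 called by DESeq2 (median -1.18, or -0.45 without vehicle replicate 1, camera adjusted p = 0.223). The 55 histone genes had no call in edgeR, also over the list alone, with 1 gene at an unadjusted p under 0.05 and 0 called by DESeq2. Their median was 0.11 and their mean -0.04, with the camera direction down (adjusted p = 0.833). The histone median was -0.08 without vehicle replicate 3 and -0.04 without ilimaquinone replicate 2. Of the histone genes 1 was called lower without vehicle replicate 1, as was 1 sperm marker.

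**Figure D3:**
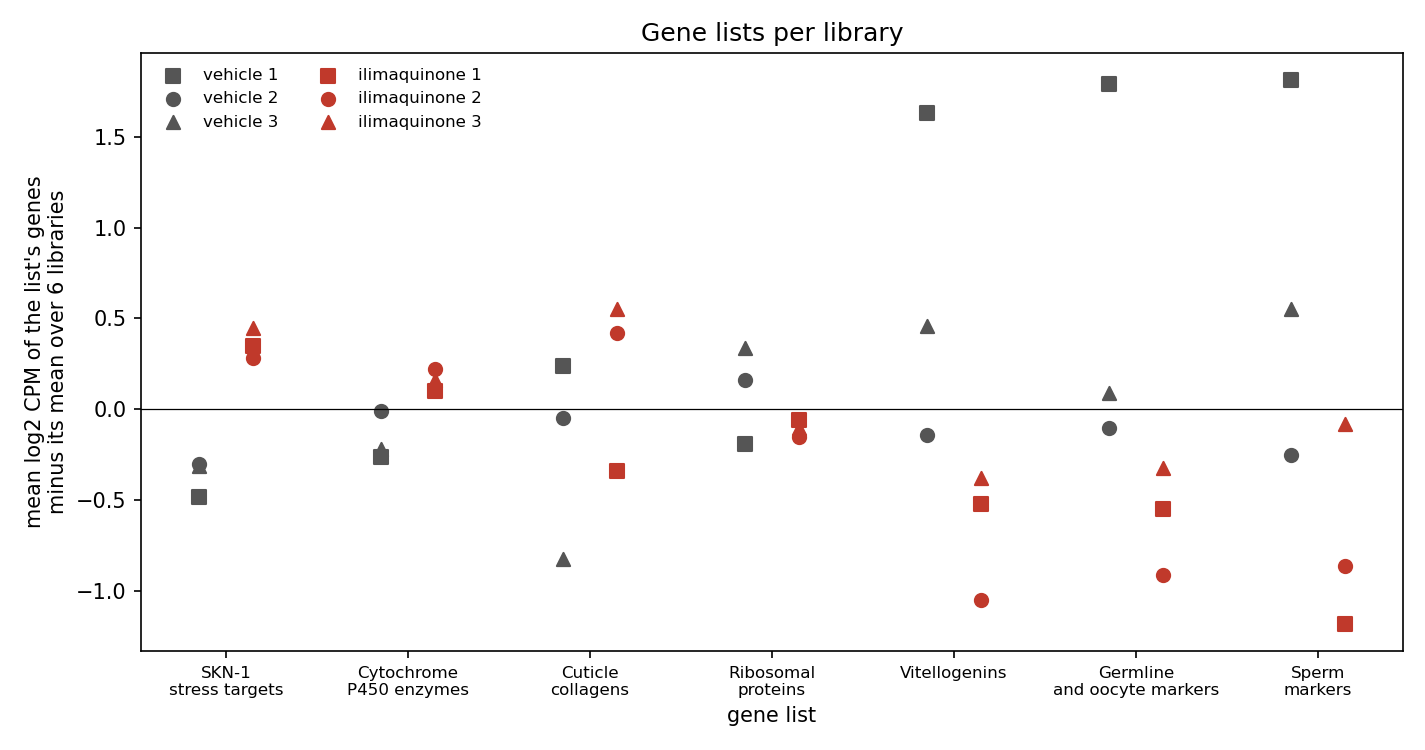
Mean log2 CPM of the genes of 7 lists in each library, minus the list's mean over the 6 libraries; grey symbols are vehicle and red symbols ilimaquinone libraries, with a square, circle and triangle for replicates 1, 2 and 3. SKN-1 targets lie between -0.48 and -0.30 in the vehicle libraries and between 0.28 and 0.45 in the ilimaquinone libraries, while germline markers reach 1.79 in vehicle replicate 1 alone.

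Genes of immune defence went both ways. Of 62 antimicrobial effector genes 4 rose and 1 fell, or 10 and 6 adjusted over the list alone. The median was 0.09 (camera adjusted p = 0.036; adjusted p = 0.624 with an estimated correlation), and 0.17 without vehicle replicate 2. The call was lost without vehicle replicate 3 (median 0.03, camera adjusted p = 0.156) and without ilimaquinone replicate 2 (median 0.02, camera adjusted p = 0.0858). It was also lost without a filter on low counts and with a stricter filter (camera adjusted p = 0.0766 and 0.128). A pair of neighbouring saposin genes on chromosome X were among those that rose. The log2 fold change was 2.22 ± 0.12 for spp-9 (edgeR adjusted p = 0.00218) and 2.78 ± 0.27 for spp-21, while the caenacin gene cnc-2 fell by 0.89 ± 0.14 on the log2 scale. Of 135 C-type lectin genes 4 rose and 2 fell, or 8 and 12 adjusted over the list alone. DESeq2 called 8 of them higher and 25 lower, and 13 were higher and 39 lower at an unadjusted p under 0.05. Their median was -0.43 (camera adjusted p = 0.0081; adjusted p = 0.624 with an estimated correlation), and the call was lost without vehicle replicate 2 (camera adjusted p = 0.0582). The lectin gene clec-18 rose from 14.7 ± 2.25 to 90.3 ± 11.8 CPM and clec-52 fell from 128 ± 15.3 to 75.2 ± 3.38 CPM. The calls without vehicle replicate 1 were 6 antimicrobial genes higher and 5 lower, and 4 lectin genes higher and 8 lower.

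Cuticle collagen genes, which build the worm's outer layer, included 12 that rose and none that fell, of 169 tested, with the same counts adjusted over the list alone. Their median was 0.59 and 118 had a positive fold change (camera adjusted p = 7.03e-06; adjusted p = 0.704 with an estimated correlation). The median was 0.31 without vehicle replicate 3 and 0.38 without ilimaquinone replicate 2. As a list the groups overlapped. Its summed level was 7373, 7333 and 3690 CPM in vehicle replicates 1, 2 and 3, and 6151, 11800 and 10560 CPM in ilimaquinone replicates 1, 2 and 3. The collagen gene with the smallest p, col-166, rose by 0.78 ± 0.09 on the log2 scale (edgeR adjusted p = 0.0206). In the fit without vehicle replicate 1, 17 collagen genes were called higher.

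Ribosomal protein genes had a median of -0.25 over 80 genes, 73 of them negative (camera adjusted p = 3.22e-05; adjusted p = 0.724 with an estimated correlation). No member was called by edgeR, also over the list alone, with 10 at an unadjusted p under 0.05 and 2 called by DESeq2. The median was -0.40 without vehicle replicate 1 and -0.14 without vehicle replicate 3. Their share of all counts was 16.3, 19.4 and 21.4% in vehicle replicates 1, 2 and 3, and at most 16.07% with ilimaquinone. The 31 proteasome genes had a median of 0.10 (camera adjusted p = 0.0425; adjusted p = 0.724 with an estimated correlation) and no member called by edgeR, also over the list alone, with 3 at an unadjusted p under 0.05 and 0 called by DESeq2. That list call was lost with other scalings (camera adjusted p = 0.0601 to 0.0983). It was also lost without vehicle replicate 2, ilimaquinone replicate 1 or ilimaquinone replicate 3 (0.337, 0.0662 and 0.185). Of 80 autophagy and lysosome genes 2 rose and 1 fell, or 11 and 1 adjusted over the list alone. The median was 0.13, or 0.07 without vehicle replicate 1 (camera adjusted p = 0.0027; adjusted p = 0.624 with an estimated correlation). The called members were the protease gene asp-18 and the proton pump gene vha-5, which rose, and the protease gene asp-12, with a log2 fold change of -0.78 ± 0.13. The autophagy gene lgg-1 had a log2 fold change of -0.14 ± 0.17. When vehicle replicate 1 was left out, 16 ribosomal protein genes were called lower, and 6 autophagy and lysosome genes were called higher and 2 lower.

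Markers of other tissues held few called genes. Of 37 sarcomere genes of muscle none was called by edgeR over all genes and 1 rose adjusted over the list alone, with 5 at an unadjusted p under 0.05 and 2 called by DESeq2. Their median was 0.05, or -0.02 without vehicle replicate 1 (camera adjusted p = 0.159, and 0.0246 without vehicle replicate 3). The myosin genes unc-54 and myo-3 had log2 fold changes of -0.16 ± 0.12 and 0.31 ± 0.22. The 24 neuron markers had a median of 0.24 (camera adjusted p = 0.0145; adjusted p = 0.724 with an estimated correlation), and without vehicle replicate 1 it was 0.06 (camera adjusted p = 0.472). None of them was called by edgeR, also over the list alone, with 3 at an unadjusted p under 0.05 and 1 called by DESeq2. The 16 intestine markers had no call in edgeR, also over the list alone, with 2 at an unadjusted p under 0.05 and 0 called by DESeq2 (median -0.11, camera adjusted p = 0.779). Of 73 pharynx gland and lining markers pqn-60 rose, by 1.21 ± 0.13 on the log2 scale, also over the list alone, while DESeq2 called 2 higher and 4 lower and 6 were higher and 6 lower at an unadjusted p under 0.05. That list had a median of 0.08 (camera adjusted p = 0.388, and 0.0493 without ilimaquinone replicate 1), and without ilimaquinone replicate 3 it was 0.00. With vehicle replicate 1 left out, 1 sarcomere gene was called higher, and 2 pharynx markers were called higher and 1 lower.

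Lipid and lifespan genes also held few. Of 21 genes of fatty acid synthesis and desaturation none was called by edgeR over all genes, with 3 at an unadjusted p under 0.05 and 3 called by DESeq2 (median -0.13, or 0.04 without vehicle replicate 2, camera adjusted p = 0.385). The desaturase gene fat-7 fell adjusted over the list alone and was at 2.66 ± 0.955 against 0.665 ± 0.113 CPM (edgeR adjusted p = 0.0538 over all genes, and 0.0377 without vehicle replicate 1). Of 41 genes of fatty acid oxidation acs-2 rose, or 3 adjusted over the list alone, while DESeq2 called 3 higher and 4 lower and the same numbers had an unadjusted p under 0.05. That list had a median of 0.00, a mean of -0.11 and the camera direction up (adjusted p = 0.86). Of 32 lifespan regulators the kinase gene akt-1 rose by 0.58 ± 0.10 on the log2 scale, or 1 rose and 2 fell adjusted over the list alone. Their median was 0.12 (camera adjusted p = 0.101, but 0.0403 without vehicle replicate 3 and 0.0446 without ilimaquinone replicate 3), and it was 0.05 without vehicle replicate 1 (camera adjusted p = 0.19). In the fit without vehicle replicate 1, 3 fatty acid oxidation genes and 2 lifespan regulators were called higher and 1 fatty acid oxidation gene and 1 fatty acid synthesis gene lower.

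In the other lists with edgeR calls, DESeq2 called 31 collagen genes higher and 5 lower, 14 and 2 P450 genes, 28 and 6 transferase genes, 3 and 3 transporters, and 12 and 3 autophagy and lysosome genes. It called 9 antimicrobial genes higher and 8 lower, 2 and 2 lifespan regulators, and 7 SKN-1 targets, 4 DAF-16 targets and 8 antioxidant genes, all higher. Over all 30 lists, camera with its preset correlation of 0.01 called 16, 11 higher and 5 lower. With an estimated correlation it called 0, with 2 lists at an unadjusted p under 0.05. Among the called lists this estimate ran from 0.04 for DAF-16 targets to 0.97 for germline and oocyte markers. It was 0.94 for vitellogenins, 0.80 for sperm markers and 0.77 for ribosomal proteins. Where the estimate lies far above the preset, the p-values at the preset can be too small. The fry test, whose directional p asks whether the genes of a list move on balance one way, called 6. Its mixed p, which asks whether they change in either direction, called 17, and neither compares the list with other genes. The 6 directional calls were SKN-1 targets, transferases, DAF-16 targets, antioxidant enzymes, endoplasmic reticulum chaperones and the Golgi list. The directional calls, given below as fry calls, depended on single libraries and on scaling. There were 6, 7 and 0 without vehicle replicate 1, 2 and 3, 0, 1 and 0 without ilimaquinone replicate 1, 2 and 3, and 1 with upper-quartile factors. In the 3 fits without a fry call 9, 8 and 8 lists had an unadjusted fry p under 0.05, and camera called 18, 16 and 17 there. Without vehicle replicate 1 camera called 15 lists, all among the 16, and lost the neuron markers.

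Transcripts were compared in the same way, to see which isoforms differed. Of 22238 tested transcripts 65 were called, 52 higher and 13 lower, from 64 genes, of which 52 were also called as genes. The gene with transcripts called in both directions was lin-1, which encodes an ETS transcription factor and was chosen after its values were seen. Its transcript NM_001027880 rose from 2.40 ± 0.480 to 44.2 ± 3.35 CPM and its transcript NM_001307372 fell from 42.5 ± 3.41 to 8.19 ± 2.59 CPM, while the gene was not called. Isoforms of a gene share sequence, so these values are estimates of how reads were divided. Without vehicle replicate 2 or 3 the test called 8 or 37 transcripts, and without ilimaquinone replicate 1, 2 or 3 it called 2, 5 or 13.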

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

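All settings here were planned; the counts of list members without vehicle replicate 1, given where they differed, were chosen only after the data were seen. Every gene called over all genes kept its direction under every setting that tested it, which their non-overlapping groups made nearly certain. The causes of the changes below were not tested unless named. DESeq2's Wald test called 879 genes higher and 943 lower, and these included all 242 genes of the edgeR calls. It also called 1485 transcripts, and its genes called with at least a 2-fold change were 989. Without a filter on low counts 60 genes were higher, 9 lower and 56 of at least 2-fold, with 31 transcripts, where more genes entered the adjustment, and a stricter filter gave 94 lower genes. Without the filter camera also called the muscle and lifespan lists (adjusted p = 0.0232 and 0.00546), and with the stricter filter it lost the proteasome list (adjusted p = 0.146). Scaling with upper-quartile factors called 164 of the 242 genes and library size alone 204.

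The labels do not say that the replicate numbers pair samples, so the main fit, fixed before the data were examined, had no block. Deviation correlations between same-numbered libraries were -0.16, 0.29 and -0.16, and 1 number of 3 paired its libraries best with each other. With a replicate block there were 21 higher genes, 1 lower gene and 22 genes of at least 2-fold, 21 of them among the 242, and 0 transcripts in edgeR, with 2610 at an unadjusted p under 0.05; DESeq2 was not run with the block. The block also ended the camera calls of C-type lectins and proteasome genes (adjusted p = 0.0509 and 0.094) and left fry 0 lists, with 8 at an unadjusted p under 0.05.

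Leaving out each library in turn gave 11 to 451 higher genes, 0 to 274 lower genes, 11 to 275 genes of at least 2-fold, 2 to 45 transcripts and 14 to 18 lists. Of 47 named genes that were called, 47, 31 and 22 were called without vehicle replicate 1, 2 and 3, and 8, 11 and 5 without ilimaquinone replicate 1, 2 and 3, where fewer libraries entered the fit; their largest adjusted p over these 6 fits was 0.268. With all libraries in the fit, camera with an estimated correlation called 0 lists and fry 6. Signs turned for 2 named genes that were not called. For hsp-4 the log2 fold change was -0.065 to 0.227 over the left-out libraries, negative without vehicle replicate 2 (-0.033) and without ilimaquinone replicate 3. For hsp-16.2 it was 0.007 in limma-trend on log2(TPM + 1) and -0.165 to 0.125 over the left-out libraries, positive without vehicle replicate 3 and without ilimaquinone replicates 1 and 2 (0.005 and 0.014). In simulated data with these depths, spread and numbers of libraries, 27% of 2-fold changes were recovered, and how much of this each of them accounts for was not tested.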

Other observations

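The splits of the libraries below were planned as tests; the tests of gene families, neighbouring genes, vehicle replicate 1 and body markers were chosen only after the result was seen. Beyond the fixed lists, some genes of the pals family, known from the response to intracellular pathogens, rose. Of 35 tested pals genes 11 were called, all higher, where their number predicted 0.513, and 30 had a positive fold change. Among 205 symbol families of at least 8 tested genes this was the strongest excess (one-sided Fisher's exact test, adjusted p = 3.36e-10), followed by collagens of the col family at 12 of 151 (adjusted p = 2.39e-04). Fisher's exact test takes genes as independent, but pals genes include neighbours and similar copies measured in the same libraries. Its p-values can therefore be too small. pals-6 rose from 33.3 ± 4.89 to 93.8 ± 7.64 CPM, pals-14 by 1.55 ± 0.21 and pals-4 by 2.34 ± 0.19 on the log2 scale, while pals-22 and pals-25, known regulators of that response, had log2 fold changes of 0.02 ± 0.20 and -0.02 ± 0.18 and were not called. Called genes also lay side by side: 30 adjacent pairs of tested genes were called in the same direction, against a median of 2 and a maximum of 10 in 10000 random placements (permutation p = 1e-04, the smallest they can give), the longest run being col-167, col-168, col-169 and col-170 on chromosome X. Some of these pairs overlap or, like numr-1 and numr-2, are near-identical, so shared reads stay open for them.

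A candidate explanation for the pals genes that is technical is the spread of reads from a single changed gene over similar copies. The fold changes of the called genes ran from 1.22 to 3.09 on the log2 scale (heterogeneity p = 9.97e-08, Cochran's Q, n = 11 genes, a chi-square approximation whose errors rest on 3 libraries per group), but reads shared with copies of different level would give unequal folds as well, so shared reads cannot be told apart from changes of several genes. Vehicle replicate 1 alone does not explain them, since 11 of the 11 were also called without it. The same held for 241 of all 242 called genes, so this is not particular to the pals genes. The loci of pals-3 and pals-4 overlap, so those values are uncertain. A response to the compound and an infection of the treated animals remain open as hypotheses, and neither was tested.

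The lower oocyte and yolk markers could come from vehicle replicate 1 alone. Without it the difference of mean log2 CPM over these lists was -0.628, against -1.206 with all libraries. Vehicle replicates 2 and 3, at 4.77 and 5.03, still lay above the ilimaquinone libraries, at 4.33, 3.94 and 4.55. In that fit no vitellogenin or germline marker was called lower. Camera called the vitellogenin and germline lists at its preset correlation (adjusted p = 0.00135 and 3.20e-10). With an estimated correlation it called neither (adjusted p = 0.667 for each), nor did fry (adjusted p = 0.25 and 0.218). With so few libraries left, whether vehicle replicate 1 is the only source cannot be decided. For sperm markers the difference without it was -0.857, against -1.412, and vehicle replicate 2, at 1.01, lay below ilimaquinone replicate 3, at 1.18, so for these the contribution of that library cannot be told apart from that of the treatment. A smaller germline in the treated animals is an untested hypothesis, and a different age or brood state of the animals in vehicle replicate 1 stays open as well.

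The higher SKN-1 targets could reflect a larger share of body tissue where the germline is smaller. Their median fold change exceeded that of 77 muscle, intestine and neuron markers by 0.775 (0.87 against 0.10). Their lower quartile, 0.28, lay at about the upper quartile of these markers, 0.27. These values argue against a larger share of muscle, intestine and neurons as the whole source. Cuticle collagens, which were not among the markers, had a median of 0.59 and an upper quartile of 1. A larger share of tissue outside the markers therefore stays open. Without vehicle replicate 1 the difference of mean log2 CPM was 0.668, against 0.725, and all 3 ilimaquinone libraries still lay above the other vehicle libraries. Induction through SKN-1 by the quinone is a hypothesis consistent with these values, and skn-1 activity itself was not tested.

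With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Every split but the real one mixes vehicle and ilimaquinone libraries in both groups. A difference between the treatments then adds to the spread within groups and lowers the counts, so low counts there do not measure chance. For genes higher, genes lower and genes of at least 2-fold, 1 of the 10 splits gave as many as the real one, which is the real split itself, with 188, 54 and 143 genes against at most 1, 1 and 1 in any other split. For lists it was also 1 split, with 16 lists against at most 15, so other groupings of these libraries called nearly as many lists, and for transcripts 1 split, with 65 against at most 3.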
